A study of Mus musculus with 32 samples.

How the data were processed

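Gene expression was measured in 32 samples of LPS-activated mouse splenic B cells, 1 array each, in 15 groups: activated cells labelled as baseline and 7 compounds at 2 times, each given with IFNα. The deposited values are intensities on a linear scale (6.19 to 19735), one per probe set and array, which had been summarized with Affymetrix Power Tools and RMA, per the submitters' processing notes, which state no versions. Their log2 was computed here for every test and list mean. Of 24922 probe sets, the 21425 that the platform table assigns to exactly 1 gene symbol were tested, covering 19752 genes. The 1399 probe sets with several symbols and the 2098 without an entry were left out, and for this reason Isg15, Stat1 and Jak3, among others, have no value. Symbols were checked against a RefSeq table through Entrez identifiers (21347 probe sets matched, 0 symbols changed). No genome build is stated, so no positions are given.

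Analyses ran in R 4.3.3 with limma 3.58.1. A single linear model held 15 group means over the 32 arrays, and contrasts were tested with moderated statistics (lmFit and eBayes, constant prior variance, 17 residual and 4.16 prior degrees of freedom). Each compound was compared with baseline at each time (14 contrasts) and with IFN.6226 (12 contrasts), JAK1 with TYK2 and PAN with JAK1/JAK2 (4 contrasts), and 8 h with 2 h with equal weight per compound. Changes of the compound differences with time were tested with an F test over 6 contrasts and singly. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each contrast, with calls at an adjusted p under 0.05. Calls of at least 2-fold were counted as well.

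The same model with the array set (low or high median) as an additive block has 16 residual and 6.00 prior degrees of freedom, and is given beside it as chosen after the array medians were seen. Both baseline arrays lie in the low-median set, so the block estimates the set difference from the inhibitor groups alone. Within-set differences compare single arrays, or 1 with 2, and are values without a test, except for 8 h against 2 h, where compound and time were additive terms. Reduced range means a log2 interquartile range more than 0.3 under the median of the array's set. The closest arrays of 1 group, replicates 2 and 3 of IFN.6226 at 2 h, differed by 0.153 (root mean square, log2). No array therefore holds the same values as another of its group, and arrays of different groups were not compared in this way.

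Gene lists were written down before the data were examined: ISG core, IRF1 and GBP, JAK-STAT components, STAT5 and common gamma chain targets, MHC class I presentation, MHC class II presentation, NF-kB and LPS response, Immediate early, Cell cycle, MYC and ribosome biogenesis, Plasma cell programme, B cell identity, Unfolded protein and integrated stress response, p53 targets, Glycolysis and hypoxia, Cholesterol synthesis, T cell markers, Myeloid markers, Dendritic cell markers, NK cell markers, and Erythroid and platelet markers (21 lists). A gene with several probe sets (921 genes) was represented by the one with the highest mean. ISG core held 40 measured genes, IRF1 and GBP 14 and Cholesterol synthesis 13. Lists were tested with fry, which asks whether the members move in one direction and does not compare them with other genes, adjusted over all lists and contrasts of a family. Camera with the preset correlation of 0.01 and with an estimated correlation, which does compare members with other genes, stands beside it. List members were counted over all genes tested and adjusted over the list alone. The 95% intervals of list means came from a linear model of the list means per array.

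Genes were named by a rule fixed at the same stage. For IFN.6226 against baseline up to 10 rises and 10 falls with the largest differences were taken among called probe sets in which every array of the group lay beyond every reference array. For the other compounds against baseline up to 3, and for comparisons between compounds up to 5, followed the same rule. For 8 h against 2 h up to 10 each way were taken among those with the same direction for all 7 compounds, and for the F test the 10 with the smallest adjusted p. Fixed names were Ifit1, Ifit3, Mx1, Oasl1, Rsad2, Irf7, Usp18, Stat2, Irf9, Irf1, Socs1, Cxcl10, Cish, Jak1, Jak2 and Tyk2, together with the 2 largest and 2 smallest changes in a list where it is described. Unnamed transcripts, olfactory and vomeronasal receptors and immunoglobulin or T cell receptor segments were counted and not named.

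The tests were tried on simulated data with the same design and array sets, 21425 probe sets and 100 changed probe sets per size. Noise was drawn independently for each probe set around an additive set difference, without correlation between genes and without reduced-range arrays. The simulation therefore does not cover false calls of lists of correlated genes or false calls caused by such arrays. For JAK1 against IFN.6226 at 2 h the model without the block recovered 20% of changes of log2 1 and 70% of log2 2 and called 0 unchanged probe sets, and the blocked model recovered 88% and 99% and called 11. For 8 h against 2 h the shares were 93% and 100% with 1 unchanged call, and 100% and 100% with 9. A list lowered by 1 was estimated at −0.97 without and −0.92 with the block, and 0 and 1 of 20 other lists were called.

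Alternatives fixed beforehand were the replicate number as a block, a second quantile normalization, removal of array medians, removal of the dimmer probe sets, use of all probe sets, 1 probe set per gene, eBayes with trend and robust settings, models of arrays of 1 time only, IFN.6228 as the reference, ISG core without the genes of ISGF3, the list median, both forms of camera, and each array left out in turn. Added after the data were seen were the array-set block, each array set alone, and the blocked model without reduced-range arrays or without PAN 2 h replicate 2.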

Results

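Mouse B cells from the spleen of 6-week-old C57BL/6 males, purified by negative selection, were activated with lipopolysaccharide (LPS, a bacterial cell wall component) at 10 µg/ml for 48 h. The cells then received interferon-α (IFNα) at 100 U/ml together with 1 of 7 compounds labelled as inhibitors of Janus kinases (JAKs), each at its IC80 (80% inhibitory concentration), for 2 h or 8 h. The IFNα receptor signals through the kinases JAK1 and TYK2, whereas JAK3 serves receptors that hold the common gamma chain. The labelled targets were JAK1 (IFN.3404), TYK2 (IFN.2845), JAK1 and JAK2 (IFN.6221, JAK1/JAK2), all JAKs (IFN.6222, PAN), JAK2 (IFN.3885) and JAK3 (IFN.6226 and IFN.6228). RNA of 32 samples was measured on 1 Affymetrix Mouse Gene 1.0 ST array each. IFN.6226 had 3 arrays per time, every other compound 2 per time, and activated cells labelled as baseline 2. Cells labelled as given IFNα without an inhibitor were not analysed here, so a difference from baseline holds the effects of IFNα, compound and culture time together. IFN.6226 therefore served as the second reference, a choice made with the tests and gene lists before the data were examined. The labels do not state that replicates came from separate cultures, so every p-value measures the spread between these samples, and the number of arrays per group limits precision.

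The arrays fell into 2 sets of 16 that differed in overall intensity. Median intensity was 107 to 125 in the low-median set, which held both baseline arrays and the first replicate of each of the 14 inhibitor groups. It was 167 to 193 in the high-median set, which held the others. The first principal component carried 68.4% of the variance and separated these sets. The median difference from baseline over all probe sets was 0.25 to 0.37 on the log2 scale, and −0.03 to 0.04 once array set entered the model as a block. Differences are given from the model without this block, as fixed beforehand, unless the block is named. Counts mostly follow with it, but most single-gene values do not. Since both baseline arrays are in the low-median set, differences from baseline without the block also hold the set difference. IFN.6226 has 2 of its 3 arrays per time in the high-median set, so differences from it without the block hold part of the set difference too. The median difference from IFN.6226 over all probe sets was −0.12 to −0.08, and −0.03 to 0.01 with the block. With IFN.6226 at 2 h Ifit3 stood 23.7-fold above baseline without the block and 16.1-fold with it, and Usp18 11.3-fold and 9.9-fold. The block was chosen after seeing the data and lowered the median residual SD from 0.380 to 0.169. The range of intensities was reduced in 5 arrays, which were kept. They were replicate 2 of PAN at 2 h, replicate 2 of JAK1 at 8 h, replicates 2 and 3 of IFN.6226 at 8 h and replicate 1 of IFN.6228 at 8 h. PAN at 2 h was the furthest out, with a log2 interquartile range of 1.94 on its replicate 2, where the median of its set was 3.04.

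Interferon-stimulated genes rose in cells given IFNα with the JAK3 inhibitor IFN.6226 for 2 h (n = 3), compared with baseline (n = 2). Ifit3, an interferon-induced tetratricopeptide protein, rose 23.7-fold (log2 difference 4.57, SE 0.50, adjusted p = 2.17e-05; 4.01 with the block). The antiviral GTPase gene Mx1 rose 12.6-fold (3.65, SE 0.32, adjusted p = 1.13e-06). Usp18, whose product dampens type I interferon signalling, rose 11.3-fold (3.50, SE 0.29, adjusted p = 5.26e-07). Rsad2 (3.39), Rtp4 (2.99), Mx2 (2.73), Ifit3b (2.67) and Ifit2 (2.64) rose as well, as did Slfn5 (SE 0.41, adjusted p = 3.19e-04) and the metallothionein gene Mt2 (3.66). The cytokine gene Il6 fell by 1.83 (SE 0.33, adjusted p = 0.00865). Of the 40 measured genes of the list ISG core, 24 rose (37 when adjusted over the list alone). The list mean rose by 1.67 (95% interval 1.19 to 2.14, fry adjusted p = 1.99e-04), and by 1.47 with the block, where 31 genes rose. Over all genes 67 probe sets were higher and 1 lower (138 and 11 with the block), nearly all by at least 2-fold (65 and 1). Without Baseline replicate 1, 25 calls were left.

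At the same time the other compounds divided by how far these genes stood above baseline (n = 2 each). With the JAK2 inhibitor Ifit3 rose by 4.61 (SE 0.55, adjusted p = 8.56e-05) and Mx1 by 3.64. With IFN.6228 Ifit3 rose by 4.18 (adjusted p = 4.14e-04) and Mx1 by 3.37. With the TYK2 inhibitor Usp18 rose by 2.03 (SE 0.32, adjusted p = 0.00838). Ifit3 stood at −0.11 (adjusted p = 0.935) with the JAK1 inhibitor. Mt2 nevertheless rose with that compound, 13.4-fold (3.74, SE 0.37, adjusted p = 2.68e-05), together with Id2 (2.18, adjusted p = 0.00485), an inhibitor of DNA binding, and Skil (1.67, adjusted p = 0.00555), a regulator of TGF-β signalling. Mt2 also rose with the TYK2 inhibitor (3.97), IFN.6228 (3.81), the JAK2 inhibitor (3.58), JAK1/JAK2 (3.40) and PAN (3.26), all against the same 2 baseline arrays. Il6 fell by 2.29 with PAN (adjusted p = 0.0268) and was also lower with the TYK2 inhibitor (SE 0.36, adjusted p = 0.0171). The Il6 calls with IFN.6226, PAN and TYK2 were lost after quantile normalization and after removing array medians, and the Skil call after the latter.

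The list ISG core followed the same order at 2 h. It rose by 1.675 with the JAK2 inhibitor (fry adjusted p = 3.05e-04), where 20 of 40 genes rose (35 over the list alone), and by 1.53 with the block. With IFN.6228 it rose by 1.54 (fry adjusted p = 5.92e-04), with 15 genes (36 over the list alone). With the TYK2 inhibitor ISG core differed by 0.77, not called by fry (fry adjusted p = 0.0922, 2 genes, 15 over the list alone). It was called with the block (0.62, fry adjusted p = 0.0148, 7 genes, 15 over the list alone), after quantile normalization (0.53) and by camera without the block (adjusted p = 0.0298 with an estimated correlation). The difference was not called with JAK1/JAK2 (0.63, fry adjusted p = 0.233), PAN (0.31, 0.716) or the JAK1 inhibitor (−0.03, 95% interval −0.55 to 0.49, 0.933). JAK1/JAK2 was called after quantile normalization (0.38, fry adjusted p = 0.0158) and with the replicate number as a block (0.0153). Without the reduced-range arrays the blocked model called ISG core lower with the JAK1 inhibitor (−0.21) and higher with JAK1/JAK2 (0.45) and PAN (0.53). Without the block limma called 0 ISG core genes over all genes in each of the 3 and, over the list alone, 6, 5 and 0. Probe sets higher and lower than baseline numbered 6 and 0 with the JAK1 inhibitor (42 and 7 with the block), 9 and 1 with TYK2 (48 and 6), and 5 and 0 with JAK1/JAK2 (47 and 2). They numbered 1 and 1 with PAN (26 and 73), 51 and 0 with JAK2 (125 and 7), and 35 and 0 with IFN.6228 (105 and 10). Quantile normalization changed the split to 39 and 6 for TYK2 and 32 and 20 for PAN, and removing array medians to 10 and 0 for TYK2 and 2 and 1 for PAN. Leaving out 1 array at a time gave 1 to 4 calls for JAK1, 1 to 3 for TYK2, 1 to 2 for JAK1/JAK2, 12 to 35 for JAK2 and 8 to 23 for IFN.6228. The count reached 2151 for PAN without its replicate 1.

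**Figure D1:**
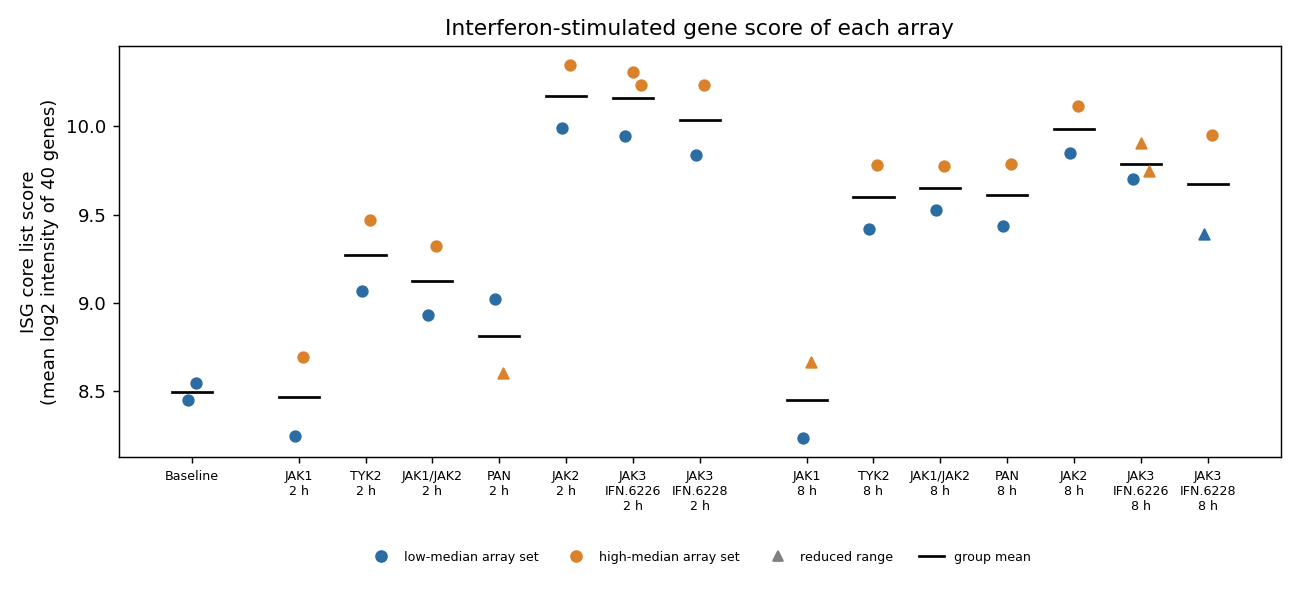
Mean log2 intensity of the 40 measured ISG core genes on each array, by compound and time, with the 2 array sets marked. Baseline cells averaged 8.50, cells given the JAK1 inhibitor for 2 h 8.47 and cells given IFN.6226 for 2 h 10.16.

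After 8 h the interferon-stimulated genes stood above baseline with every compound except the JAK1 inhibitor. With IFN.6226 (n = 3, baseline n = 2) Ifit3 rose by 3.29 (SE 0.50, adjusted p = 0.00244), Rtp4 by 2.36 and Irf7, a transcription factor of the interferon response, by 1.92, a call lost after removing array medians. With the JAK2 inhibitor Ifit3 rose by 3.53 and Usp18 by 3.04, and with IFN.6228 Ifit3 rose by 2.82 (not called with 1 probe set per gene) and Mx1 by 2.50. Usp18 rose by 2.33 with the TYK2 inhibitor and by 2.34 with JAK1/JAK2, and Mx1 rose by 1.98 with PAN. ISG core rose by 1.49 with JAK2 (fry adjusted p = 6.22e-04, 17 of 40 genes, 39 over the list alone) and by 1.29 with IFN.6226 (0.00100, 15 and 38). It rose by 1.15 with JAK1/JAK2 (0.00582, 6 and 36) and by 1.10 with TYK2 (0.00603, 8 and 35). With PAN it rose by 1.115 (0.00603, 6 and 32) and with IFN.6228 by 1.175 (0.00582, 7 and 34). In the blocked model these differences were 0.97 and 1.03. With the JAK1 inhibitor ISG core stood at −0.05 (fry adjusted p = 0.874, 0 genes, 0 over the list alone), and at −0.26, a call, in the blocked model without reduced-range arrays. These calls were lost without replicate 2 of the compound for PAN (fry adjusted p = 0.102), TYK2 (0.0925), IFN.6228 (0.0814) and JAK1/JAK2 (0.0623). Without Baseline replicate 1 they were lost as well (0.0625, 0.0631, 0.0528 and 0.0528). Removing array medians ended the TYK2 call (ISG core 0.80, fry adjusted p = 0.0606).

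Idi1 was lower than baseline after 8 h with all 7 compounds, and Elovl6 and Acaca with some of them. Idi1, which encodes an isomerase of the sterol pathway, fell by 1.69 with the JAK1 inhibitor (SE 0.20, adjusted p = 7.14e-04), by 1.72 with TYK2 and by 1.38 with IFN.6226 (SE 0.18, adjusted p = 8.36e-04), and least with IFN.6228 (by 1.17, adjusted p = 0.0148). The fatty acid elongase gene Elovl6 fell by 1.61 with IFN.6228 and fell by 1.40 with JAK2. Acaca, encoding acetyl-CoA carboxylase, fell by 1.21 with IFN.6226, and the scramblase gene Plscr1 fell by 0.94 (adjusted p = 0.0367). Removing array medians ended the calls of Plscr1 and, with all 7 compounds, of Idi1. Mt2 remained higher, by 2.85 with the JAK1 inhibitor (adjusted p = 8.58e-04) and by 2.55 with IFN.6226. The 13 measured genes of the list Cholesterol synthesis were lower on average with TYK2 (−1.04, fry adjusted p = 0.00603, 3 genes, 11 over the list alone) and JAK1 (−1.03, 0.00603, 1 and 10). They were also lower with IFN.6228 (−0.92, 0.0155, 1 and 10) and IFN.6226 (−0.90, 0.00884, 2 and 10). Cholesterol synthesis was called by fry with the block and not without it for JAK2 (−0.90, 4.76e-04, 8 and 12), JAK1/JAK2 (−0.84, 7.77e-04, 7 and 12) and PAN (−0.78, 0.00167, 6 and 11).

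The counts at 8 h depended on how the arrays were scaled. Probe sets higher and lower than baseline numbered 29 and 7 with IFN.6226, where the block gave 70 and 74, quantile normalization 83 and 77 and removal of array medians 13 and 18. In that order the counts were 1 and 2 with JAK1 (24 and 34, 31 and 34, 1 and 4) and 16 and 6 with TYK2 (85 and 114, 77 and 103, 6 and 14). With JAK1/JAK2 they were 10 and 2 (73 and 18, 48 and 21, 12 and 1), and with PAN 8 and 2 (67 and 17, 45 and 19, 9 and 2). With JAK2 they were 29 and 3 (84 and 18, 64 and 22, 18 and 3), and with IFN.6228 13 and 5 (73 and 72, 72 and 74, 11 and 8). Without Baseline replicate 1 the IFN.6226 count was 1. Leaving out 1 array at a time gave 3 to 4 for TYK2, 0 to 2 for JAK1/JAK2, 0 for PAN, 6 to 15 for JAK2, 0 to 8 for IFN.6228 and 2 to 5 for JAK1.

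Set against IFN.6226 at 2 h (n = 3), the JAK1 inhibitor (n = 2) gave much lower interferon-stimulated genes. Ifit3 fell by 4.67 (SE 0.50, adjusted p = 1.17e-05), and within the low-median and high-median sets it stood at −4.64 and −4.48. Mx1 fell by 4.53 (SE 0.32, adjusted p = 2.89e-08), Usp18 fell by 4.21 and Rtp4 fell by 3.48. Irf7 fell by 1.43 (adjusted p = 0.0215) and Irf9, a subunit of the interferon-activated complex ISGF3, fell by 0.99 (adjusted p = 0.0267). Irgm1, of the list IRF1 and GBP, fell by 2.13. Of the 40 ISG core genes 19 fell (36 over the list alone), and the list mean was lower (95% interval −2.17 to −1.22, fry adjusted p = 1.29e-04; within sets −1.70 and −1.58). Sp100 (−0.43), Ifih1 (−0.41) and Oas1a (−0.58) were among the smallest differences in ISG core. Altogether 35 probe sets were lower and 0 higher (81 and 0 with the block), and without JAK1 replicate 1, 17 were left.

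PAN, JAK1/JAK2 and TYK2 lay between the 2 ends at 2 h (n = 2 each). Against IFN.6226, Mx1 fell by 1.98 with the TYK2 inhibitor (SE 0.32, adjusted p = 0.0262) and by 2.43 with PAN. Ifit2 fell by 2.17 with JAK1/JAK2 (adjusted p = 0.0119) and fell by 2.58 with PAN, where the sets gave −1.80 and −3.17. Ifit3 fell by 2.64 with PAN (adjusted p = 0.0295). Rsad2 fell by 1.59 with TYK2 and by 1.98 with JAK1/JAK2, and Cmpk2, a mitochondrial nucleotide kinase, fell by 1.36 with TYK2 and by 1.77 with JAK1/JAK2. The TYK2 call of Rsad2 and both Cmpk2 calls were lost after removing array medians. ISG core was lower with TYK2 (−0.89, fry adjusted p = 0.0376, 3 genes, 26 over the list alone), with −0.88 and −0.80 within sets, a call lost after removing array medians (−0.78, 0.0877). It was lower with JAK1/JAK2 (−1.04, 0.0110, 5 and 31) and with PAN (−1.35, 8.90e-04, 20 and 37), with −1.02 and −0.95 within sets for the first and −0.93 and −1.67 for PAN. For PAN in the blocked model adjusted p = 0.0536 with an estimated correlation. The TYK2 call was lost without TYK2 replicate 1 (fry adjusted p = 0.615), TYK2 replicate 2 (0.0559), IFN.6226 replicate 2 (0.188) or IFN.6226 replicate 3 (0.149). The JAK1/JAK2 call was lost without JAK1/JAK2 replicate 1 (0.364), IFN.6226 replicate 2 (0.0654) or IFN.6226 replicate 3 (0.0522). No probe set was higher, and the lower ones numbered 3 with TYK2 (25 with the block), 6 with JAK1/JAK2 (34) and 28 with PAN. PAN gave 63 higher and 159 lower with the block, 2 and 73 after quantile normalization and 0 and 37 after removing array medians. Leaving out 1 array gave 0 to 2 for TYK2 and 0 to 6 for JAK1/JAK2, and for PAN 0 without its replicate 2 and 2156 without its replicate 1.

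**Figure D2:**
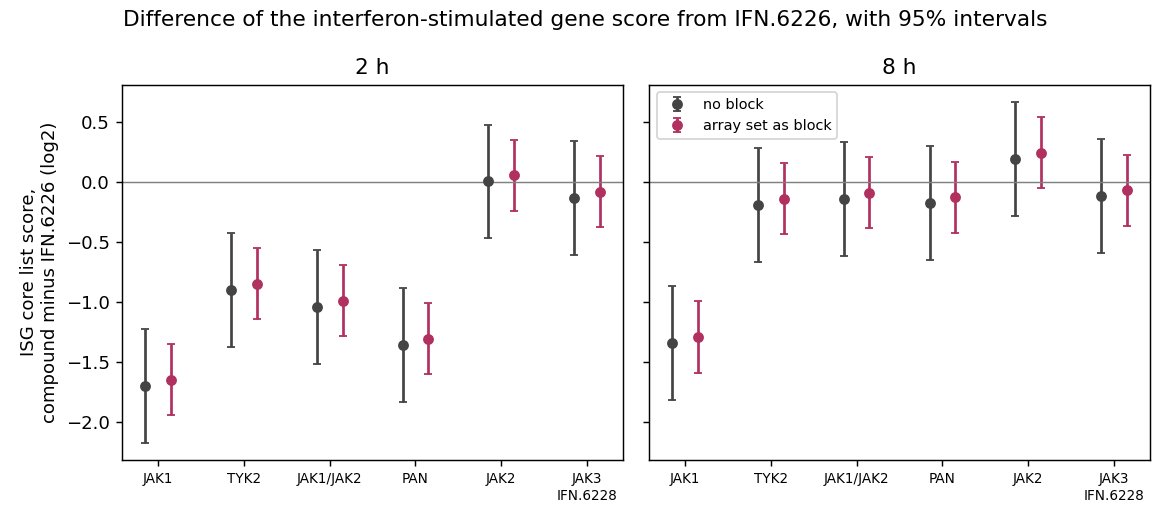
Difference of the ISG core mean from IFN.6226 in log2 units with 95% intervals, for each compound at 2 h and 8 h. The JAK1 inhibitor lay at −1.34 at 8 h, and PAN moved from −1.35 at 2 h to −0.17 at 8 h.

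After 8 h the JAK1 inhibitor differed from IFN.6226 in interferon-stimulated genes (n = 2 and 3). Ifit3 fell by 3.42 (SE 0.50, adjusted p = 0.00198), Usp18 fell by 3.16 (adjusted p = 6.97e-06), Irf7 fell by 2.44 (adjusted p = 7.84e-05), Mx1 fell by 2.39 and Rsad2 fell by 2.35. ISG core was lower (−1.34, fry adjusted p = 8.90e-04), with 15 of 40 genes called and 35 over the list alone (27 and 38 with the block). In total 24 probe sets were lower and 0 higher (48 and 1 with the block). Leaving out 1 array gave 7 (without JAK1 replicate 1) to 18. The ISG core difference was −0.19 with TYK2 (95% interval −0.66 to 0.29), −0.14 with JAK1/JAK2 (−0.61 to 0.34), −0.17 with PAN (−0.65 to 0.30) and 0.20 with JAK2 (−0.28 to 0.67). None of these was called in either model. In the blocked model without the reduced-range arrays, which leaves 1 IFN.6226 array at 8 h, ISG core was called lower with TYK2 (−0.28), PAN (−0.27) and JAK1/JAK2 (−0.23). Probe sets called there numbered 6 with TYK2, 5 with JAK1/JAK2 and 2 with PAN, and 14 with PAN when PAN 2 h replicate 2 was the array left out. With all arrays limma called 0 probe sets at 8 h for TYK2, JAK1/JAK2, PAN and JAK2, in both models, while 33, 60, 72 and 20 had an unadjusted p under 0.05 (773, 3158, 2657 and 1056 with the block). With the JAK2 inhibitor at 2 h limma likewise called 0 (1 unadjusted, 52 with the block), and the ISG core difference was 0.01 (95% interval −0.47 to 0.48).

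The 2 compounds labelled as JAK3 inhibitors were compared with each other at both times (n = 2 and 3). IFN.6228 minus IFN.6226 gave an ISG core difference of −0.13 at 2 h (95% interval −0.60 to 0.35) and −0.11 at 8 h (−0.59 to 0.36). With the block the intervals were −0.37 to 0.22 and −0.36 to 0.23, so differences of those sizes are not excluded. Limma called 0 probe sets at 2 h (0 with an unadjusted p under 0.05, 29 with the block) and 0 at 8 h (52, and 606 with the block). At 8 h the blocked model without the reduced-range arrays kept 1 array per compound. The IFN.6228 array lies in the high-median set and the IFN.6226 array in the low-median set. Their difference there rests on the additive set term, so calls from it cannot be read as a difference between the compounds.

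Cells given the JAK1 inhibitor also had lower interferon-stimulated genes than cells given the TYK2 inhibitor (n = 2 each). At 2 h Usp18 fell by 2.73 (SE 0.32, adjusted p = 4.33e-04), Mx1 fell by 2.56 and Rtp4 fell by 2.31. At 8 h Usp18 fell by 2.59, Irf7 fell by 2.42, Rtp4 fell by 1.99 and the syndecan gene Sdc3 fell by 1.67, with the Irf7 and Sdc3 calls lost after removing array medians. ISG core was lower at 8 h (−1.15, fry adjusted p = 0.0117), with 6 genes called and 33 over the list alone (23 and 37 with the block). This call was lost without TYK2 replicate 2 (0.191) or JAK1 replicate 1 (0.176). The 2 h difference was −0.80 (95% interval −1.32 to −0.28), not called by fry (fry adjusted p = 0.184, 3 genes, 15 over the list alone). It was called with the block (fry adjusted p = 0.00443, 9 genes, 24 over the list alone), after quantile normalization (−0.78) and by camera without the block (adjusted p = 1.81e-06 with an estimated correlation). Lower probe sets numbered 3 at 2 h (15 with the block) and 10 at 8 h (39, with 1 higher), and 0 to 2 and 0 to 9 when 1 array was left out. PAN and JAK1/JAK2 differed in ISG core by −0.32 at 2 h (fry adjusted p = 0.996) and by −0.04 at 8 h (95% interval −0.56 to 0.48). Within the sets the 2 h difference was 0.09 and −0.72. Between PAN and JAK1/JAK2 limma called 0 probe sets at either time (1197 and 2 with an unadjusted p under 0.05, 9233 and 81 with the block). Without PAN replicate 1 it called 1820 at 2 h.

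Between 2 h and 8 h, averaged over the 7 compounds (15 arrays per time), genes of the list Cholesterol synthesis fell. The desaturase gene Fads2 fell by 1.86 (SE 0.16, adjusted p = 2.43e-07). Enzymes of sterol synthesis fell, Lss by 1.60, Fdps by 1.28 and Idi1 by 1.19 (SE 0.07, adjusted p = 3.12e-09). Msmo1 fell by 1.17, the phosphatase gene Dusp4 fell by 1.28, Zhx2 and the histone demethylase gene Kdm6b each fell by 1.23, and Bcor fell by 1.14. Nqo1, a quinone oxidoreductase, rose by 1.23 (SE 0.13, adjusted p = 3.52e-06) and Pirb, an inhibitory receptor, by 1.02. Rgs18 (0.97), Zfc3h1 (0.96), Rasgrp2 (0.96), Rnase6 (0.86), Cd55 (0.85), Nucb2 (0.82) and Gsap (0.81) rose less. Il6 rose by 0.86 (adjusted p = 4.21e-04). All 13 measured genes of Cholesterol synthesis fell, in both models and over the list alone, from 0.49 for Srebf2, which encodes a regulator of the pathway, to 1.60 for Lss. The list mean fell by 1.01 (SE 0.09, 95% interval −1.21 to −0.82, fry adjusted p = 1.99e-08), with −1.05 and −0.97 within the sets. Each of the 15 arrays at 8 h had a lower Cholesterol synthesis mean (9.76 or less) than each of the 15 at 2 h (9.89 or more). Overall 324 probe sets rose and 348 fell, 5 and 22 of them by at least 2-fold. The block gave 1595 and 1388, and removal of array medians 405 and 577. Within the low-median set 1691 rose and 1439 fell, and within the high-median set 83 and 126.

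**Figure D3:**
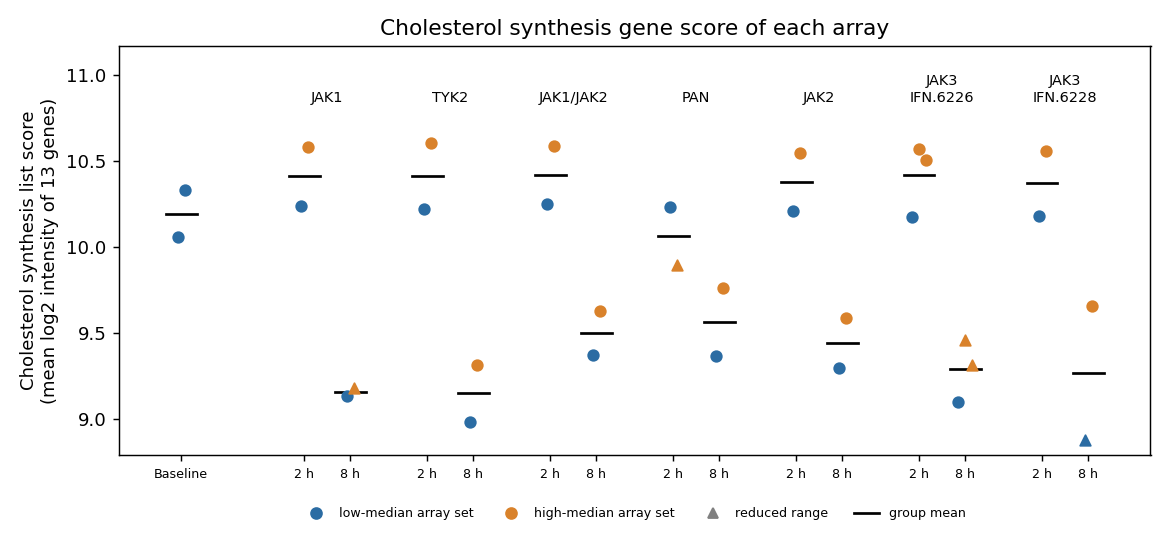
Mean log2 intensity of the 13 measured genes of Cholesterol synthesis on each array, by compound and time. Baseline cells averaged 10.19.

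The list MYC and ribosome biogenesis was also lower at 8 h than at 2 h (−0.31, fry adjusted p = 0.0371, adjusted p = 0.264 with an estimated correlation). Of its 19 measured genes 6 fell, and over the list alone 15 fell and 1 rose. Cad (−0.59), Rrp12 (−0.55) and Nolc1 (−0.50) had the largest differences, while Npm1 (0.02) and Nop56 (0.01) hardly differed. Among other list members Nr4a1, an early response gene, fell by 1.06 (SE 0.12, adjusted p = 1.10e-05), and the cytokine signalling suppressor gene Socs2 fell by 0.91 (SE 0.07, adjusted p = 1.02e-07). Egr3 fell by 0.56 and Ldha, lactate dehydrogenase, fell by 0.42. The class II genes H2-Ob and H2-DMa rose by 0.52 and 0.50, and the macrophage gene Adgre1 rose by 0.54. Further lists were called between the times by fry with the block and not without it. Glycolysis and hypoxia was lower (−0.21, fry adjusted p = 0.00140, adjusted p = 0.159 with an estimated correlation), with 7 of 13 genes down, and 8 down and 1 up over the list alone. Immediate early was lower (−0.16, 0.00326, adjusted p = 0.426 with an estimated correlation), with 5 of 18 down and 2 up, and 8 and 3 over the list alone. STAT5 and common gamma chain targets was lower (−0.11, 0.00839, adjusted p = 0.678 with an estimated correlation), with 4 of 14 down and 2 up, and 4 and 3 over the list alone. MHC class II presentation was higher (0.18, 0.00224, adjusted p = 0.426 with an estimated correlation), with 4 of 9 up and 5 over the list alone. Myeloid markers was higher (0.10, 0.00224, adjusted p = 0.426 with an estimated correlation), with 2 of 12 up. ISG core was not called between the times (0.10, fry adjusted p = 0.568), with 5 genes up and 3 down, and 15 and 5 over the list alone.

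The change of interferon-stimulated genes from 2 h to 8 h was not the same for every compound in the blocked model. Relative to IFN.6226, Ifit2 rose with time by 2.30 more with PAN, and by 1.64 more without PAN 2 h replicate 2 (adjusted p = 0.00507). ISG core gained 1.18 with PAN (fry adjusted p = 0.00219 with the block, 0.130 without, adjusted p = 0.463 with an estimated correlation), with 34 genes called and 37 over the list alone. Without PAN 2 h replicate 2 the ISG core gain with PAN was 0.79 (fry adjusted p = 2.14e-04, 6 genes), and without all reduced-range arrays it was 0.64, with 0.75 for JAK1/JAK2. ISG core gained 0.90 with JAK1/JAK2 (0.0125 and 0.538, 5 genes and 32) and 0.71 with TYK2 (0.0353 and 0.576, 0 genes and 21). The ISG core change was not called in either model for JAK1 (0.36), JAK2 (0.19) or IFN.6228 (0.01). Over all 6 compounds limma's F test called 0 probe sets without the block (98 with an unadjusted p under 0.05) and 12 with it (2620). Among the 12 were Ifit3 (adjusted p = 5.62e-04), Mx1, Cmpk2 and Mx2 (each 0.00144), the death ligand gene Tnfsf10 (0.00359), Ifit2 (0.00403), Usp18 (0.00964), Rsad2 (0.0169), Irgm1 (0.0250) and Rnf213 (0.0263). Taken singly in the blocked model, the change with time differed from that of IFN.6226 at 5997 probe sets for PAN (3248 higher and 2749 lower), 6 for JAK1/JAK2, 1 for JAK1 and 0 for the others. Without PAN 2 h replicate 2 the PAN count was 9. Without the block the F test called 49 when PAN 2 h replicate 1 was left out.

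The 14 measured genes of the list IRF1 and GBP, targets of the transcription factor IRF1 and guanylate-binding proteins, were called as a list by fry with the block and not without it. At 2 h Cxcl10, a chemokine, rose over baseline by 2.52 with IFN.6226 (SE 0.34, adjusted p = 3.47e-04) and Irgm1 by 1.84, while Gbp3 stood at 0.36 and Gbp5 at 0.39, neither called. Irf1 stood at 1.45 (adjusted p = 0.0947; 1.14, adjusted p = 0.00374 with the block), and another Irf1 probe set at 0.44 (adjusted p = 0.622). List differences in the rest of this paragraph are from the blocked model. IRF1 and GBP stood 0.58 above baseline with IFN.6226 (fry adjusted p = 8.63e-06, 3 genes and 7 over the list alone). Without the block the difference was larger, with list means of 8.51 with IFN.6226 and 7.63 at baseline (fry adjusted p = 0.0540). With the block IRF1 and GBP stood 0.58 above baseline with JAK2 (1.21e-05, 3 and 7) and 0.50 above with IFN.6228 (4.85e-05, 3 and 4). At 8 h the IRF1 and GBP difference was 0.36 with JAK2 (4.99e-04), 0.34 with IFN.6226 (5.53e-04), 0.33 with IFN.6228 (0.00192), 0.25 with PAN (0.0126) and 0.25 with JAK1/JAK2 (0.0144), with 1 gene each. Against IFN.6226 at 2 h it was −0.56 with JAK1 (5.04e-06, 3 and 7) and −0.55 with PAN (1.11e-05, 5 and 9; adjusted p = 0.0675 with an estimated correlation), the latter −0.38 with 1 gene without PAN replicate 2. With JAK1/JAK2 it was −0.42 (1.46e-04, 2 and 5), with TYK2 −0.41 (1.07e-04, 2 and 4), and at 8 h −0.28 with JAK1 (0.00467, 1 and 3).

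Among the other genes fixed beforehand, Ifit1 rose over baseline by 2.46 with IFN.6226 at 2 h (adjusted p = 0.00449), Oasl1 by 1.26 (0.0124), Irf7 by 1.83 (9.52e-04) and Irf9 by 1.00 (0.0163). Stat2 stood at 1.06 (0.487), the feedback gene Socs1 at 0.77 (0.622) and Cish, a target of STAT5, at 0.36 (0.622). None of the measured kinase genes was called, with Jak1 at 0.25 (0.622), Jak2 at 0.35 (0.622) and Tyk2 at 0.16 (0.696). In the JAK1 comparison with IFN.6226 at 2 h Ifit1 stood at −1.71 (adjusted p = 0.202; −1.60, adjusted p = 1.02e-06 with the block) and Oasl1 at −0.86 (0.491). The array as annotated has no probe set for Isg15, Stat1 or Jak3 alone.

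Few of the remaining lists were called by fry, and these with the block and not without it. Against baseline at 8 h MHC class II presentation, the antigen display genes of B cells, was called with PAN (0.49, fry adjusted p = 0.00843), JAK1/JAK2 (0.47, 0.0111) and JAK2 (0.46, 0.0126), with 1 gene over all genes and 5 over the list alone in each. It was also called with IFN.6226 (0.35, 0.0496, 2 genes, adjusted p = 0.202 with an estimated correlation). MYC and ribosome biogenesis was called with TYK2 at 8 h (−0.54, 0.0234, 6 genes, 11 over the list alone, adjusted p = 0.0567 with an estimated correlation). Myeloid markers was called with the JAK1 inhibitor at 2 h against baseline (−0.23, 0.0112, 0 genes) and against IFN.6226 (−0.19, 0.0303, 1 gene, Mpeg1). Without the block its mean with JAK1 at 2 h lay above baseline (6.84 and 6.78), so the direction against baseline depends on the block. PAN at 2 h against IFN.6226 gave lower JAK-STAT components (−0.50, 0.0184, 3 genes, 11 over the list alone, adjusted p = 0.832 with an estimated correlation), a call lost without PAN replicate 2 (−0.17, fry adjusted p = 0.229). It also gave lower MHC class I presentation (−0.38, 0.0443, 0 genes, 9 lower and 1 higher over the list alone, adjusted p = 0.832 with an estimated correlation), likewise lost without that array (−0.11, 0.587). The lists Cell cycle, Plasma cell programme, B cell identity, Unfolded protein and integrated stress response, p53 targets, Dendritic cell markers, NK cell markers and Erythroid and platelet markers were called in none of the 37 comparisons. Their lowest fry adjusted p was 0.576 without and 0.0560 with the block, and their mean differences between 8 h and 2 h lay from −0.02 to 0.06.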

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

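Tests of the interferon recovery against array sets, reduced-range arrays and a fall with IFN.6226 alone, of the PAN lists and the PAN count without 1 array, and the blocked model itself, were chosen only after the results were seen. The items here come from tests of whether a compound's difference from IFN.6226 changed between 2 h and 8 h, and they are given from the blocked model. By fry the lists were not called without the block. For ISG core the change was 0.7081 with TYK2, 0.9017 with JAK1/JAK2 and 1.179 with PAN. For IRF1 and GBP it was 0.3329 with JAK1/JAK2 (fry adjusted p = 0.0353; 0 genes over all genes, 2 over the list alone; adjusted p = 0.0433 with an estimated correlation) and 0.4567 with PAN (fry adjusted p = 0.00907; 6 genes up and 1 down; adjusted p = 0.642 with an estimated correlation). PAN also gave JAK-STAT components 0.6185 (fry adjusted p = 0.0353; 7 genes, 14 over the list alone), MHC class I presentation 0.5537 (0.0353; 7 up and 1 down, 11 and 1 over the list alone), NF-kB and LPS response 0.5754 (0.0353; 10 genes, 11 over the list alone), STAT5 and common gamma chain targets 0.5386 (0.0327; 5 and 5) and T cell markers −0.5106 (0.0353; 4 genes down, 8 over the list alone), each with adjusted p = 0.642 with an estimated correlation. The F test over all 6 compounds called 12 probe sets, and also made calls with the replicate block (9), after quantile normalization (8) and after removing array medians (3).

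The first pattern is that TYK2, JAK1/JAK2 and PAN lay below IFN.6226 in ISG core at 2 h and closer to it at 8 h. Each compound has the same number of arrays from each set at 2 h and at 8 h, so an additive set difference cancels from this pattern. The array-set test therefore says little about such a difference. It shows that the pattern was present in both sets, where the 8 h difference was at most 0.321 of the 2 h difference. Without the reduced-range arrays the difference still changed by at least 0.5564 (TYK2, from −0.84 to −0.28, 95% interval of the change 0.40 to 0.72; 0.75 with JAK1/JAK2 and 0.64 with PAN). A fall with IFN.6226 (−0.38 from 2 h to 8 h) makes up part of the change. It does not account for all of it, since within each set the list mean of the 3 compounds itself rose, by at least 0.3103. A biological hypothesis for the rise, inhibition that lessened between 2 h and 8 h, stays open, and others were not weighed. It was not tested, since cells given IFNα alone were not analysed here and compound levels were not measured in these arrays.

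The second pattern is the 5997 probe sets whose change with time differed between PAN and IFN.6226. The replicate 2 array of PAN at 2 h, which had the most reduced range, accounts for it. Without that array 9 were called, and without replicate 1 15607. Without it the calls of 5 lists ended, with changes of 0.3031 for JAK-STAT components, 0.2879 for MHC class I presentation, 0.2505 for NF-kB and LPS response, 0.2951 for STAT5 and common gamma chain targets and −0.2998 for T cell markers. IRF1 and GBP kept 0.64 of its change, the highest share of the 6 lists, and its call (0.2925, fry adjusted p = 0.0128), so that array carries part of these list changes and the rest stays open. No biological explanation was tested for them.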

How the results depend on the processing

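Tests with the array-set block, within each array set, without reduced-range arrays and without PAN 2 h replicate 2 were chosen only after the results were seen. Changing to 1 probe set per gene kept every count within 1.5 times. ISG core without the measured ISGF3 genes, which are only Stat2 and Irf9, kept every call and direction. The list median kept every direction. It has no test of its own and takes the fry p of the list, so its calls could not differ. Calls of 122 named genes and comparisons were fitted again in up to 12 alternatives each, not with arrays left out in turn or within 1 array set. Trend and robust eBayes and models of 1 time leave a gene's difference as it was and alter only its test. The same holds without the dimmer probe sets, using all probe sets and with 1 probe set per gene. None of the calls changed direction, which is informative only for the other alternatives. All were kept with the replicate block, with array set as block and under trend and robust eBayes, as were the 117 that stayed in the test without the dimmer probe sets. Calls of named genes were lost in 44 of 102 cases in models of 1 time each, where fewer arrays estimate the variance, in 23 of 122 after removing array medians (9 genes, Idi1 at 8 h with every compound among them) and in 7 of 23 in the reference swap (TYK2, JAK1/JAK2 and PAN at 2 h). They were lost in 3 of 122 after quantile normalization (Il6 each time), and in 1 of 122 each using all probe sets and 1 probe set per gene (Ifit3 with IFN.6228 at 8 h). Counts and ISG core values below are those that differ from the report, grouped by alternative, and the cause was not tested unless stated. Signal over background limits the dimmer probe sets, and leaving them out raised each count that moved, with fewer probe sets tested. Same-numbered inhibitor arrays deviated together in 170 of 172 pairs (correlation over 0.1) but in only 3 of 27 pairs with baseline, whose 2 arrays both lie in the low-median set, so the numbers do not pair all samples and, among inhibitor arrays, largely repeat the array sets.

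With the replicate block, calls against baseline came to 61 with JAK1, 92 with TYK2, 89 with JAK1/JAK2, 6210 with PAN, 222 with JAK2, 244 with IFN.6226 and 170 with IFN.6228 at 2 h. Counterparts with the replicate block at 8 h were 78 with JAK1, 182 with TYK2, 182 with JAK1/JAK2, 160 with PAN, 130 with JAK2, 160 with IFN.6226 and 171 with IFN.6228. Against IFN.6226 with the replicate block, calls came to 71 with JAK1, 19 with TYK2, 32 with JAK1/JAK2 and 107 with PAN at 2 h. At 8 h with the replicate block it was 49 with JAK1. Calls with the replicate block came to 14 for JAK1 against TYK2 at 2 h and 36 for JAK1 against TYK2 at 8 h, and 2336 for 8 h against 2 h and 9 for the F test. ISG core with the replicate block gained a call at 0.77 with TYK2 and 0.63 with JAK1/JAK2 against baseline at 2 h, and −0.80 for JAK1 against TYK2 at 2 h. With array set as block, calls against baseline came to 49 with JAK1, 54 with TYK2, 49 with JAK1/JAK2, 99 with PAN, 132 with JAK2, 149 with IFN.6226 and 115 with IFN.6228 at 2 h. Counterparts with array set as block at 8 h were 58 with JAK1, 199 with TYK2, 91 with JAK1/JAK2, 84 with PAN, 102 with JAK2, 144 with IFN.6226 and 145 with IFN.6228. Against IFN.6226 with array set as block, calls came to 81 with JAK1, 25 with TYK2, 34 with JAK1/JAK2 and 222 with PAN at 2 h. At 8 h with array set as block it was 49 with JAK1. Calls with array set as block came to 15 for JAK1 against TYK2 at 2 h and 40 for JAK1 against TYK2 at 8 h, and 2983 for 8 h against 2 h and 12 for the F test. ISG core with array set as block gained a call at 0.62 with TYK2 against baseline at 2 h, and −0.80 for JAK1 against TYK2 at 2 h.

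After a second quantile normalization, calls against baseline came to 36 with JAK1, 45 with TYK2, 34 with JAK1/JAK2, 52 with PAN, 115 with JAK2, 134 with IFN.6226 and 107 with IFN.6228 at 2 h. Counterparts after a second quantile normalization at 8 h were 65 with JAK1, 180 with TYK2, 69 with JAK1/JAK2, 64 with PAN, 86 with JAK2, 160 with IFN.6226 and 146 with IFN.6228. Against IFN.6226 after a second quantile normalization, calls came to 75 with JAK1, 27 with TYK2, 36 with JAK1/JAK2 and 75 with PAN at 2 h. At 8 h after a second quantile normalization it was 60 with JAK1. Calls after a second quantile normalization came to 15 for JAK1 against TYK2 at 2 h and 40 for JAK1 against TYK2 at 8 h, and 2492 for 8 h against 2 h and 8 for the F test. ISG core after a second quantile normalization gained a call at 0.53 with TYK2 and 0.38 with JAK1/JAK2 against baseline at 2 h, and −0.78 for JAK1 against TYK2 at 2 h. After removing array medians, calls against baseline came to 39 with IFN.6226 at 2 h. Counterparts after removing array medians at 8 h were 5 with JAK1 and 21 with JAK2. Against IFN.6226 after removing array medians, calls came to 10 with TYK2 and 14 with JAK1/JAK2 at 2 h. Calls after removing array medians came to 6 for JAK1 against TYK2 at 2 h, and 3 for the F test. ISG core after removing array medians lost its call at 0.80 with TYK2 against baseline at 8 h, and −0.78 with TYK2 against IFN.6226 at 2 h. ISG core after removing array medians changed sign at −0.00198 with PAN against baseline at 2 h, and 0.0663 with JAK1/JAK2 and 0.011 with PAN against IFN.6226 at 8 h. Without the dimmer probe sets, calls against baseline came to 13 with JAK1, 16 with JAK1/JAK2, 4 with PAN and 57 with IFN.6228 at 2 h. Counterparts without the dimmer probe sets at 8 h were 15 with JAK1, 43 with TYK2, 26 with JAK1/JAK2, 35 with PAN, 55 with JAK2 and 33 with IFN.6228. Against IFN.6226 without the dimmer probe sets, calls came to 8 with TYK2 and 51 with PAN at 2 h. Calls without the dimmer probe sets came to 9 for JAK1 against TYK2 at 2 h, and 1065 for 8 h against 2 h. Against IFN.6226 using all probe sets, calls came to 39 with JAK1 at 8 h. Calls using all probe sets came to 24 for JAK1 against TYK2 at 8 h. Under trend and robust eBayes, calls against baseline came to 11 with JAK1, 10 with JAK1/JAK2 and 4 with PAN at 2 h. Counterparts under trend and robust eBayes at 8 h were 6 with JAK1, 37 with TYK2, 22 with JAK1/JAK2 and 16 with PAN. Against IFN.6226 under trend and robust eBayes, calls came to 7 with TYK2 and 43 with PAN at 2 h. In models of 1 time each, calls against baseline came to 1 with JAK1, 1 with TYK2, 1 with JAK1/JAK2, 1 with PAN, 32 with JAK2 and 38 with IFN.6226 at 2 h. Counterparts in models of 1 time each at 8 h were 0 with JAK1, 4 with TYK2, 1 with JAK1/JAK2, 1 with PAN, 15 with JAK2, 15 with IFN.6226 and 2 with IFN.6228. Against IFN.6226 in models of 1 time each, calls came to 0 with TYK2, 2 with JAK1/JAK2 and 11 with PAN at 2 h. At 8 h in models of 1 time each it was 10 with JAK1. Calls in models of 1 time each came to 1 for JAK1 against TYK2 at 2 h and 2 for JAK1 against TYK2 at 8 h. Against IFN.6228 in the reference swap, calls came to 0 with TYK2, 2 with JAK1/JAK2 and 9 with PAN at 2 h. At 8 h in the reference swap it was 14 with JAK1.

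ISG core by camera at the preset correlation gained a call at −0.0284 with JAK1, 0.77 with TYK2 and 0.63 with JAK1/JAK2 against baseline at 2 h, and −0.049 with JAK1 against baseline at 8 h, and 0.00834 with JAK2 and −0.13 with IFN.6228 against IFN.6226 at 2 h, and −0.19 with TYK2, −0.17 with PAN and 0.20 with JAK2 against IFN.6226 at 8 h, and −0.80 for JAK1 against TYK2 at 2 h, −0.32 for PAN against JAK1/JAK2 at 2 h and −0.0382 for PAN against JAK1/JAK2 at 8 h. ISG core by camera at an estimated correlation gained a call at 0.77 with TYK2 against baseline at 2 h, and −0.80 for JAK1 against TYK2 at 2 h. Camera compares the list with other genes. Without the block the median over all probe sets lay above baseline in the comparisons with baseline. It lay below IFN.6226 in the comparisons with that compound (−0.12 to −0.08). For PAN against JAK1/JAK2 this median was 0.02 at 2 h and 0.01 at 8 h, and for JAK1 against TYK2 at 2 h −0.0008.

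Calls within the low-median set came to 3130 for 8 h against 2 h. ISG core within the low-median set moved by more than the spread at 0.90 with IFN.6228 against baseline at 8 h, and −0.93 with PAN against IFN.6226 at 2 h, and 0.0899 for PAN against JAK1/JAK2 at 2 h. Calls inside the high-median set came to 209 for 8 h against 2 h. ISG core inside the high-median set moved by more than the spread at −1.67 with PAN against IFN.6226 at 2 h, and −0.72 for PAN against JAK1/JAK2 at 2 h. In the blocked model without reduced-range arrays, calls against baseline came to 549 with JAK1, 686 with TYK2, 492 with JAK1/JAK2, 320 with PAN, 779 with JAK2, 1046 with IFN.6226 and 847 with IFN.6228 at 2 h. Counterparts in the blocked model without reduced-range arrays at 8 h were 567 with JAK1, 1950 with TYK2, 1005 with JAK1/JAK2, 1279 with PAN, 921 with JAK2, 641 with IFN.6226 and 2979 with IFN.6228. Against IFN.6226 in the blocked model without reduced-range arrays, calls came to 175 with JAK1, 115 with TYK2, 119 with JAK1/JAK2 and 81 with PAN at 2 h. At 8 h in the blocked model without reduced-range arrays they were 99 with JAK1, 6 with TYK2, 5 with JAK1/JAK2, 2 with PAN and 1507 with IFN.6228. Calls in the blocked model without reduced-range arrays came to 48 for JAK1 against TYK2 at 2 h and 103 for JAK1 against TYK2 at 8 h, and 5755 for 8 h against 2 h and 302 for the F test. ISG core in the blocked model without reduced-range arrays gained a call at −0.21 with JAK1, 0.60 with TYK2, 0.45 with JAK1/JAK2 and 0.53 with PAN against baseline at 2 h, and −0.26 with JAK1 against baseline at 8 h, and −0.28 with TYK2, −0.23 with JAK1/JAK2 and −0.27 with PAN against IFN.6226 at 8 h, and −0.80 for JAK1 against TYK2 at 2 h. ISG core in the blocked model without reduced-range arrays changed sign at 0.0728 for PAN against JAK1/JAK2 at 2 h. In the model blocked and lacking PAN 2 h replicate 2, calls against baseline came to 62 with PAN at 2 h. At 8 h this came to 198 with PAN. Against IFN.6226 in the model blocked and lacking PAN 2 h replicate 2, calls came to 14 with PAN at 8 h. Calls in the model blocked and lacking PAN 2 h replicate 2 came to 4773 for 8 h against 2 h and 23 for the F test. ISG core in the model blocked and lacking PAN 2 h replicate 2 gained a call at 0.53 with PAN against baseline at 2 h. ISG core in the model blocked and lacking PAN 2 h replicate 2 changed sign at 0.072 for PAN against JAK1/JAK2 at 2 h. Some groups were then left with 1 array, assumed to vary like the others, as for IFN.6228 against IFN.6226 at 8 h. Without reduced-range arrays, those left for these compounds at 8 h came from opposite array sets, so their difference rests on the additive set term.

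Leaving out each array in turn, calls against baseline came to 1 to 3 with TYK2, 1 to 4 with JAK1, 12 to 35 with JAK2, 1 to 2 with JAK1/JAK2, 1 to 2151 with PAN, 25 to 64 with IFN.6226 and 8 to 23 with IFN.6228 at 2 h. Counterparts leaving out each array in turn at 8 h were 3 to 4 with TYK2, 2 to 5 with JAK1, 6 to 15 with JAK2, 0 to 2 with JAK1/JAK2, 0 with PAN, 1 to 23 with IFN.6226 and 0 to 8 with IFN.6228. Against IFN.6226 leaving out each array in turn, calls came to 0 to 2 with TYK2, 17 to 32 with JAK1, 0 to 6 with JAK1/JAK2 and 0 to 2156 with PAN at 2 h. At 8 h leaving out each array in turn it was 7 to 18 with JAK1. Calls leaving out each array in turn came to 0 to 2 for JAK1 against TYK2 at 2 h, 0 to 9 for JAK1 against TYK2 at 8 h and 0 to 1820 for PAN against JAK1/JAK2 at 2 h, and 477 to 805 for 8 h against 2 h and 0 to 49 for the F test. With each array left out in turn, ISG core against baseline came to −0.25 to 0.20 with JAK1 at 2 h. Counterparts with each array left out in turn at 8 h were 0.92 to 1.28 with TYK2, −0.26 to 0.17 with JAK1, 1.03 to 1.28 with JAK1/JAK2, 0.94 to 1.29 with PAN and 0.90 to 1.46 with IFN.6228. Against IFN.6226 with each array left out in turn, ISG core came to −1.09 to −0.69 with TYK2, −0.17 to 0.19 with JAK2, −1.23 to −0.84 with JAK1/JAK2 and −0.33 to 0.0727 with IFN.6228 at 2 h. At 8 h with each array left out in turn they were −0.35 to 0.00279 with PAN and −0.39 to 0.17 with IFN.6228. ISG core with each array left out in turn came to −1.37 to −0.94 for JAK1 against TYK2 at 8 h and −0.22 to 0.14 for PAN against JAK1/JAK2 at 8 h. A group left with 1 array was assumed to vary like the other groups.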

Other observations

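For the fall of Cholesterol synthesis from 2 h to 8 h, the tests of array sets, reduced-range arrays, intensity and an interferon-driven change, and the blocked model used below, were chosen only after the result was seen. The list mean fell by 1.01 over its 13 genes. An additive set difference cancels from this fall, since each compound has the same number of arrays from each set at both times. Within the array sets the smaller of the 2 differences was −0.9708, so the fall was present in both. Without the reduced-range arrays it was −1.004 (95% interval −1.07 to −0.94), so these arrays do not account for it. A shift that depends on intensity is excluded as well: at most 0.01% of random lists of like intensity fell as far, the smallest share that 10000 lists can give, and the lowest random list stood at −0.28. A change driven by interferon would be smaller with the JAK1 inhibitor, where ISG core did not rise, but the fall there was 1.11 times that with IFN.6226 (−1.25 and −1.13). This ratio has no interval, and both groups hold reduced-range arrays at 8 h. In the low-median set the list mean went from 10.24 to 9.14 with JAK1 and from 10.18 to 9.10 with IFN.6226. In the same set it went from 10.25 to 9.38 with JAK1/JAK2 and from 10.23 to 9.37 with PAN, where ISG core did rise by 8 h. Over all arrays it went from 10.42 to 9.50 with JAK1/JAK2 and from 10.06 to 9.56 with PAN. The PAN mean at 2 h over all arrays includes the array with the most reduced range, which stood at 9.89. Time after activation, with the medium and cell density that go with it, remains a hypothesis that was not tested.

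For the count of probe sets between 8 h and 2 h, other splits of the arrays were drawn within compounds. Without the block, 5 of 100 splits (the real one included) gave as many as the real 672, up to 15330, so chance is not excluded by that count. The other 4 gave several times the real count and placed 2, 3, 4 and 11 of the 14 low-median inhibitor arrays at 8 h, where the real split places 7, which points to the array sets as a structure of the samples, although 4 further splits that placed 4 gave 0. Each of the 25 other splits that placed 7 gave 0. With the block only the real split reached its 2983 calls, 1 of 100, and the highest other gave 536. That is the smallest share 100 splits can give, in a model chosen after the data were seen. It makes chance an unlikely source of that count but does not exclude it.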
